A study of Oryza sativa with 6 samples.

How the data were processed

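Total RNA was extracted from leaves of 3 wild-type and 3 ddm1a-1/ddm1b-1 rice plants or pools of plants (the labels do not say which), depleted of ribosomal RNA and made into directional libraries that were sequenced on an Illumina HiSeq instrument, per the labels' protocols. TopHat2 2.0.9 and Cufflinks 2.1.1 are named in the submitters' processing notes, with no role or order. TopHat2 is a spliced read aligner and Cufflinks is a program that assembles transcripts and estimates their abundance. The genome build and the gene annotation are not given in the sources used here. The authors deposited 1 table of genes by samples whose name gives the unit as FPKM, which scales fragments by transcript length and by the mapped total of a library.

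Samples were assigned to genotypes from their titles before the data were examined. The table's 6 value columns were then matched by name against every label of every sample. None matched, so all 6 columns were left out of every step, and 0 columns were used. Column order was not used to assign a genotype, since no label ties it to the samples. Expression values were not used either, since groups made from them could not then be compared on the same values. The planned test, a limma fit to log2 values with its alternative pseudocounts, filters, scalings, replicate block and omissions of single libraries, was therefore not run. The planned tests of gene lists and the planned count of genes off in one genotype and on in the other were not run either. The rule for naming genes was not applied for the same reason. It covered the mutated genes, the largest passing changes in each direction, a few members of each list and genes that turn on or off. Parts of the rule also needed gene descriptions, which were not available here.

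The identifier column alone was read, with Python 3.11.15. Identifiers were sorted into classes by their fixed text and counted, and the chromosome field of each locus identifier was read from its digits. The reference gene table used here does not hold locus identifiers of this style. Hence 0 of the identifiers were found in it, and no gene names or coordinates were attached to them. This does not show that the genes themselves are missing from the reference. The gene lists had been written from general knowledge with locus identifiers beforehand, and their members were counted in the table by exact identifier. Those names were not checked against an annotation.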

Results

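RNA was profiled in leaves of field-grown rice of the japonica cultivar Nipponbare at 3 weeks of age. The study comprised 6 samples in 2 groups, with 3 wild-type samples and 3 samples of the ddm1a-1/ddm1b-1 mutant. DDM1 proteins are chromatin remodelers of the SNF2 family that are needed to maintain cytosine DNA methylation, and in plants their loss is known to release transposable elements from silencing. The series title places the data in a study of adenine DNA methylation and its association with rice gene expression, development and stress responses. The comparison implied by the design was therefore of leaf transcript levels between the mutant and the wild type.

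That comparison was not made here. The table analysed held 6 columns of expression values, and these were named by a running sample number alone. A search of the labels of all 6 samples found 0 of the 6 column names. The genotype behind each column was thus not known. No label says that the columns follow the order of the samples, so their order could not assign it. Expression levels were not used to assign it, since groups made from them could not then be compared on the same values. With no genotype assigned to any column, no transcript level, fold change or count of changed genes is reported for either genotype. The mutated genes were not examined as a check of the genotype labels, because that check needs labelled columns. Depth per library was not determined.

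What the table covered could be described from its identifiers. It listed 39884 entries, all under distinct identifiers when capitals and small letters were told apart. Of these, 37809 entries (94.80%) carried a rice locus identifier beginning LOC_Os, and 4 more carried the same style of identifier in capitals. Whether entries of different classes stand for the same locus was not checked. A further 1781 entries (4.47%) were named as new genes, with a number in place of a locus identifier. How this class was defined was not determined. The remaining entries were 213 models named EVM and 77 named Add_EVM. The locus identifiers carried the numbers 1 to 12 as their chromosome field, and the number of loci per field ranged from 2190 for 9 to 4892 for 1. Of 149 genes placed on lists before the data were examined, 140 had their locus identifier in the table. The pairing of gene and identifier came from general knowledge and was not checked against an annotation. A match therefore shows that the identifier was present, not that it belongs to the named gene. Subjects of the lists included DNA methylation, the circadian clock, flowering time, abiotic stress, defence, photosynthesis, senescence, cell division and markers of other organs. Expression of the listed genes was not analysed here. Further planned lists, defined by words in gene descriptions, could not be formed without such descriptions.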

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

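No comparison between the genotypes was made, so the other pseudocounts, filters, scalings and omissions of single libraries chosen before the data were examined were not run. No paired analysis was possible because the table's columns carry neither a genotype nor a replicate number of the labels. The labels also do not say that equal replicate numbers pair plants of the 2 genotypes. The matching of columns to samples was repeated in looser ways chosen after the column names had been seen. With spaces, case and punctuation ignored, 0 of the 6 columns matched a sample. With the trailing number of a column set against the replicate number in the titles, 0 columns matched 1 sample alone. The titles use the same replicate numbers in both genotypes, so a number that matched at all matched 2 samples, 1 of each genotype. That last setting could therefore not have tied a column to 1 sample. The count of listed genes present in the table was 140 both by exact identifier and with case ignored. Since 4 locus identifiers alone were written in capitals, ignoring case had little room to add matches.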
